A study of Mus musculus with 15 samples.

How the data were processed

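RNA was measured in 15 libraries of primary mouse kidney proximal tubule cells, in 4 groups by sex and Diet1 genotype: male WT (n = 4), male KO (n = 3), female WT (n = 4) and female KO (n = 4). Per the labels, RNA was isolated with Trizol and an RNeasy kit, and strand-specific libraries were made from mRNA. The authors deposited whole-number counts per gene symbol, made with STAR 2.6.1 and featureCounts (version not given) on mouse build mm10 per the submitters' processing notes, which also name edgeR 3.26.8 and limma 3.40.6. The annotation and the strand setting of the counting are not stated in the sources used here. The deposited CPM values were used only for a check: they equal the counts divided by their library total, on the CPM scale, to within 1e-06. No composition scaling had been applied to either table.

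Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, with DESeq2 1.42.0 as an alternative. The comparisons, fixed gene lists, naming rule and alternatives were chosen before the data were examined. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13912 of 24421. Libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted with robust dispersion over all 4 groups. The square root of the common dispersion was 3.59%. Contrasts were KO against WT in each sex, the difference between these (interaction), and female against male within each genotype, 5 in all. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes of a contrast. Log2 fold changes are edgeR estimates, with a standard error taken as the estimate over the square root of its F statistic. CPM values of genes are TMM-scaled, except those of Xist, the Y-linked genes and Nnt, which are per library total.

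The labels do not say that replicate numbers mark anything shared between groups, and no block was used in the model. Each group is a set of technical replicates of 1 pool of cells, so the error is technical. A fit on counts summed per pool (4 pools, 1 residual degree of freedom) was made beside it.

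Gene lists written from general knowledge, 41 in number, were tested with limma's camera at its preset correlation when at least 3 members were measured. Camera with an estimated correlation and fry were run beside it. Adjustment was over 190 tests, which are 38 lists in 5 contrasts. A list's counts of called genes use the adjustment over all genes tested, with the count adjusted over the list alone beside the main ones.

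Genes were named by rule. For each sex these were the 8 with the largest fold up and the 8 down among called genes with a mean of at least 5 CPM in WT or KO and no overlap between WT and KO libraries. For both sexes they were 8 up and 8 down by the smaller of the 2 effects. For the interaction and the sex comparisons they were 5 up and 5 down, and from a list up to 2 called members in each direction with the largest fold. Predicted, cDNA-clone and date-like names were passed over. Nnt, and Col1a2 and Spp1 in females and Col4a1 in males, fall outside the rule and were chosen after their values were seen. Genes named by the interaction are also given with their effect in each sex. Positions are from GENCODE M21 on GRCm38, which held 1 gene of that symbol for 96.2% of the genes tested.

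Depth was 17648416 to 30896637 counts per library, at which 3 counts, the floor, correspond to 0.0971 to 0.170 CPM. In simulated data with the same depths and spread, edgeR recovered 78% of genes changed 1.5-fold and 91% of those changed 2-fold in the male design, and 83.8% and 91% in the female design. Of its calls 6.33% and 6.19% were genes left unchanged, and camera called 1 and 0 of 36 unchanged lists. Genes were simulated independently of each other, so the simulation cannot tell whether camera's preset correlation is too low for the real lists.

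Alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), other tests (DESeq2 Wald, limma-voom, glmTreat against a fold of 1.5), no filter and a stricter filter on low counts (5 CPM in at least 3 libraries), a fit of only the groups compared, a replicate block, and leaving out each library in turn. Malrd1 was not analysed here, nor were mitochondrially encoded genes, and 26 genes with date-like names were tested but not named. A few genes that met the naming rule are not reported here.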

Results

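Transcript counts per gene were obtained by RNA-seq from 15 libraries of primary proximal tubule cells, the kidney epithelial cells that take up most of the filtered salt, glucose, amino acids and protein. The cells came from male and female C57BL/6 mice that were wild type (WT) or lacked Diet1 (KO), and had been passaged in culture before RNA was isolated. Diet1, whose current gene symbol is Malrd1, encodes a protein that is made in the small intestine and the kidney and is known for its effect on bile acid levels. The groups were male WT (n = 4 libraries), male KO (n = 3), female WT (n = 4) and female KO (n = 4). Per the labels, cells of 3 to 4 mice were combined for each group and the mixture was divided into 4 technical replicates. Male KO has 3 libraries here, for a reason not stated in the sources used. Each group thus stands for a single pool of cells. The p-values therefore measure the spread between libraries of the same pool and cover neither differences between mice nor differences between separate cultures. Values after ± are SDs over the libraries of a group for CPM (counts scaled to a common library size of 1e+06) and standard errors for log2 fold changes.

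Library totals ran from 17981749 to 30896637 counts in male WT, 19236579 to 21691796 in male KO, 18524614 to 24884801 in female WT and 17648416 to 22467773 in female KO. Of 24421 listed genes, 5184 had no count in any library and 13912 had enough counts to be tested. Libraries of the same group correlated at 0.994 or more in log2 CPM, and no pair from different groups exceeded 0.993, so all 4 groups separated from each other by more than the spread within them. The first principal component carried 31.2% of the variance and the second 23.7%.

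**Figure D1:**
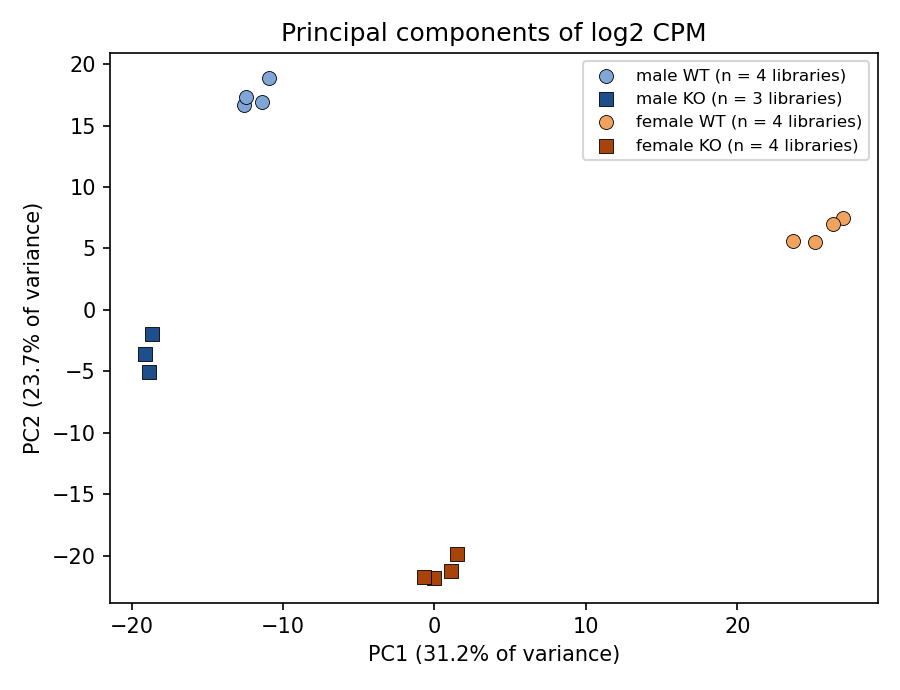
Principal components 1 and 2 of log2 CPM for the 15 libraries, with 1 point per library coloured by group and the share of variance on each axis in percent. The libraries of each group cluster together, with female WT to the right, male WT at the top and female KO at the bottom.

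Malrd1 itself was not analysed here, so the KO labels could not be checked against the targeted gene. The sex labels could be checked. Xist, the RNA that silences an X chromosome in female cells (GRCm38 chromosome X, 103460366 to 103483254), was at 631 ± 18.2 CPM in female WT (n = 4) and 602 ± 57.4 CPM in female KO (n = 4), against 0.495 ± 0.190 CPM in male WT (n = 4) and 0.517 ± 0.142 CPM in male KO (n = 3). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay between 28.9 and 75.8 CPM in the 7 male libraries and at most 4 counts in any female library. No library went against its sex label. Nnt, a mitochondrial transhydrogenase whose gene carries a deletion in C57BL/6J, had group means between 38.4 and 40.2 CPM.

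The first comparison asked which transcripts differed between KO and WT cells of male mice. Male KO cells had lower levels of genes of blood vessel endothelium, fibroblasts and extracellular matrix, and higher levels of cell cycle, cholesterol synthesis and epithelial junction genes. The strongest decrease among genes above the level for naming was in Slco5a1, a member of the organic anion transporter family (chromosome 1, 12866549 to 12992650), which was 5.59-fold lower in KO (log2 fold change -2.48 ± 0.15, edgeR adjusted p = 6.05e-14), at 2.12 ± 0.229 CPM in KO. Cdh5, the cadherin that joins endothelial cells (chromosome 8, 104101625 to 104144511), fell from 20.6 ± 1.09 to 6.71 ± 0.905 CPM (log2 fold change -1.62 ± 0.10, edgeR adjusted p = 2.53e-14). Apln, the vascular peptide apelin, fell from 27.6 ± 1.28 to 8.97 ± 0.0596 CPM, and Pecam1, an endothelial adhesion molecule, from 10.8 ± 0.561 to 3.93 ± 0.411 CPM. Lama4, a laminin chain of vascular basement membranes, and Gucy1a3, a subunit of the nitric oxide receptor, had log2 fold changes of -1.40 ± 0.13 and -1.37 ± 0.13. Decreases of similar size were found for the matrix proteins Thbs2 (-1.49 ± 0.072) and Mfap5 (-1.55 ± 0.16). The strongest increase was in Il5ra, the alpha chain of the interleukin 5 receptor (chromosome 6, 106710357 to 106749037), from 5.62 ± 0.959 to 13.2 ± 1.30 CPM (log2 fold change 1.22 ± 0.10, edgeR adjusted p = 4.25e-11). Fgfbp1, a carrier of fibroblast growth factors, rose by 1.10 ± 0.15, the lymphoid phosphatase gene Ptpn22 by 1.05 ± 0.13, and Unc13d, which acts in granule release, by 0.96 ± 0.089 on the log2 scale. Adap1 (0.94 ± 0.14), the neutrophil chemokine Cxcl1 (0.93 ± 0.13), the adhesion molecule Vcam1 (0.93 ± 0.062) and Bmp8b (0.85 ± 0.13) completed the 8 strongest increases among genes above the level for naming.

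Of 41 gene lists fixed beforehand, 38 had enough measured members, and camera was run on each in 5 comparisons with Benjamini-Hochberg adjustment over the 190 tests. It called 70, of which 35 hold with an estimated correlation, and no called list's median changed sign under the alternative scalings. Summed over the tests, 1382 member calls stood at the adjustment over all genes and 1491 adjusted over the list alone. In male cells, the endothelial list had 9 of 10 tested members lower in male KO, 0 higher and a median log2 fold change of -1.06 (9 lower adjusted over the list alone, camera adjusted p = 1.59e-18, 0.00444 with an estimated correlation). Tie1, an endothelial receptor, fell by 1.57 ± 0.20 from 3.94 ± 0.465 CPM. The fibroblast list had 8 of 10 members lower (median -0.72, 8 lower adjusted over the list alone, camera adjusted p = 3.29e-36), led by Postn, or periostin, at 27.2 ± 1.43 CPM in WT and 11.3 ± 1.09 CPM in KO, and by the collagen gene Col1a2, at 1541 ± 54.8 and 798 ± 36.2 CPM. Of 9 smooth muscle and pericyte genes, 8 were lower (median -0.29, camera adjusted p = 1.08e-12, 0.0251 with an estimated correlation), including the smooth muscle myosin Myh11 (-1.22 ± 0.066) and Rgs5 (-0.84 ± 0.20). Of 30 matrix and TGF beta target genes, 23 were lower and 2 higher (median -0.33, 24 lower and 3 higher adjusted over the list alone, camera adjusted p = 7.85e-36). The lower ones included the proteoglycan Bgn (-1.01 ± 0.054) and Lox, which crosslinks collagen (-0.89 ± 0.066), and the higher ones were Cyr61 (0.13 ± 0.025) and the cadherin Cdh2 (0.11 ± 0.027).

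Genes of DNA replication and mitosis moved together in the other direction. Of 38 cell cycle genes, 35 were higher in male KO and 0 lower, with a median log2 fold change of 0.36 (36 higher adjusted over the list alone, camera adjusted p = 2.11e-31, 3.58e-04 with an estimated correlation). Mybl2, a transcription factor of dividing cells, rose by 0.65 ± 0.10 on the log2 scale and Birc5, or survivin, from 13.9 ± 1.23 to 21.4 ± 1.78 CPM. Of 26 cholesterol synthesis and SREBP2 target genes, 21 were higher and 0 lower (median 0.26, 22 higher adjusted over the list alone, camera adjusted p = 1.88e-17, 0.0168 with an estimated correlation), among them Fdps, a prenyl pathway enzyme (0.42 ± 0.035). Of 19 epithelial junction genes, 10 were higher and 0 lower (median 0.12, camera adjusted p = 1.20e-10), led by the keratins Krt8 (0.40 ± 0.026) and Krt18 (0.37 ± 0.027). The list of tubule injury genes had 14 of 25 members higher and 3 lower (median 0.20, camera adjusted p = 9.08e-15). Vcam1 and Icam1 rose in it, while Spp1, or osteopontin, fell by 0.23 ± 0.038 and Vim by 0.19 ± 0.048. In the inflammation list 12 of 23 members were higher and 3 lower (median 0.17, camera adjusted p = 0.00250, 0.0340 with an estimated correlation). Its cytokine Il6 fell by 0.93 ± 0.17 and the chemokine Cxcl12 by 0.81 ± 0.089.

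Other lists passed in male cells with the preset correlation alone. Ribosomal protein genes, read as a sign of library quality, were higher for 41 of 51 members with a median of 0.14 (camera adjusted p = 1.90e-14, but adjusted p = 0.323 with an estimated correlation). Their share of all counts was 1.57 ± 0.0712% in male WT (n = 4) and 1.75 ± 0.0343% in male KO (n = 3). Immediate early genes, which respond to handling, had 8 of 18 members higher and 2 lower (adjusted p = 0.227 with an estimated correlation), at 0.193 ± 0.00172% and 0.206 ± 0.00434% of counts. Leukocyte genes had 4 of 12 higher, interferon-stimulated genes 9 of 27 higher, p53 targets 5 of 19 higher and respiratory chain genes 7 of 57 higher, with adjusted p = 0.133, 0.119, 0.140 and 0.725 with an estimated correlation. Podocyte genes (3 of 8 lower) and unfolded protein response genes (7 of 19 lower) had adjusted p = 0.313 and 0.227 with an estimated correlation. Of 40 differentiated proximal tubule genes, 18 had enough counts to be tested, so the result does not cover the rest. The list did not pass (camera adjusted p = 0.491), with 1 of 18 tested members higher and 3 lower. Its members included the endocytic receptor Lrp2, or megalin, which fell by 0.44 ± 0.076 on the log2 scale. Of 30 bile acid genes 15 had enough counts, of which 2 were lower in KO and 0 higher (camera adjusted p = 0.561 for the list). The bile acid receptor gene Gpbar1 fell by 0.55 ± 0.14 on the log2 scale.

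In all, 1403 genes were higher and 1405 lower in male KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), of which 29 and 112 differed by at least 2-fold. Against a fold of 1.5 as the null, 11 were higher and 70 lower. Requiring 5 CPM in at least 3 libraries gave 4 higher and 27 lower by 2-fold.

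The same question was asked of female cells. Female KO cells had higher levels of cell cycle, cholesterol synthesis and inflammatory genes than female WT cells, and lower levels of Cldn8, Kl and Scnn1b. Vcam1 (chromosome 3, 116109949 to 116129688) rose 4.19-fold, from 9.73 ± 0.912 to 41.0 ± 1.33 CPM (log2 fold change 2.07 ± 0.065, edgeR adjusted p = 9.52e-23). Mmp9, a secreted gelatinase (chromosome 2, 164940780 to 164955850), rose from 31.2 ± 1.25 to 104 ± 7.70 CPM (log2 fold change 1.73 ± 0.054, edgeR adjusted p = 2.50e-18), and the chemokine Cxcl10 from 2.87 ± 0.721 to 8.59 ± 0.584 CPM. Il5ra rose by 1.47 ± 0.11, the zinc finger gene Zbtb7c by 1.43 ± 0.088, the calmodulin-binding Pcp4 by 1.41 ± 0.15 and the imprinted Peg10 by 1.37 ± 0.084 on the log2 scale. Acta1, an actin whose coding sequence is nearly shared with other actin genes, which leaves its call uncertain, was at 32.9 ± 1.81 CPM in WT and 84.9 ± 3.93 CPM in KO. The strongest decrease was in Cldn8, a tight junction protein of the distal nephron, from 8.22 ± 0.183 to 1.63 ± 0.355 CPM (log2 fold change -2.33 ± 0.15, edgeR adjusted p = 1.35e-14). Kl, or Klotho, the co-receptor for the hormone FGF23 (chromosome 5, 150952607 to 150993817), fell from 8.13 ± 0.895 to 2.08 ± 0.680 CPM. The subunit gene Scnn1b of the epithelial sodium channel fell by 1.74 ± 0.17, the calcium pump Atp2c2 by 1.81 ± 0.14, Slco5a1 by 2.03 ± 0.14 and Serpinf1, a secreted serpin, by 1.76 ± 0.066. The sialyltransferase gene St8sia4 (-1.75 ± 0.20) and the microtubule protein gene Map2 (-1.73 ± 0.073) were also among the 8 strongest decreases above the level for naming.

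All 38 tested cell cycle genes were higher in female KO (median log2 fold change 0.77, 38 higher adjusted over the list alone, camera adjusted p = 4.74e-60, 3.29e-05 with an estimated correlation). The mitotic kinase Plk1 rose from 20.9 ± 1.28 to 42.3 ± 1.58 CPM. Of 26 cholesterol synthesis and SREBP2 target genes, 22 were higher and 1 lower (median 0.38, 22 and 1 adjusted over the list alone, camera adjusted p = 9.48e-20, 0.00993 with an estimated correlation). Fdps rose by 0.65 ± 0.033 on the log2 scale. In the inflammation list, 16 of 23 members were higher and 4 lower (median 0.39, 17 and 4 adjusted over the list alone, camera adjusted p = 4.85e-09), with the chemokine Ccl2 rising by 1.31 ± 0.14 and Icam1 by 1.10 ± 0.061. The tubule injury list had 14 of 25 higher and 6 lower (median 0.22, camera adjusted p = 1.30e-06, 0.0189 with an estimated correlation). Its lower members included Spp1 (-0.48 ± 0.035), the progenitor marker Cd24a (-0.54 ± 0.033) and Dcdc2a (-0.61 ± 0.036).

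In female KO the fibroblast list had 5 of 10 members lower and 2 higher (median -0.34, camera adjusted p = 3.12e-04, adjusted p = 0.0601 with an estimated correlation). Postn fell by 1.17 ± 0.059 and Col1a2 by 0.47 ± 0.030, while the matrix protein gene Fbln1 rose by 0.90 ± 0.18. The endothelial list did not pass (camera adjusted p = 0.291), with 3 of 10 members higher, among them the diaphragm protein gene Plvap (1.17 ± 0.16), and 0 lower. Smooth muscle and pericyte genes went both ways, 2 higher and 4 lower of 9 (camera adjusted p = 0.0596). Leukocyte genes had 7 of 12 higher and 0 lower, with adjusted p = 0.394 with an estimated correlation, and these were rare transcripts: C1qb, a complement gene of macrophages, was at 3.42 ± 0.432 CPM in WT and 6.58 ± 0.956 CPM in KO. Collecting duct principal cell genes had 3 of 5 lower (adjusted p = 0.117 with an estimated correlation), Scnn1b and Scnn1g (-1.41 ± 0.19) among them. Podocyte, thick ascending limb and distal convoluted tubule lists did not pass, with 3 higher and 2 lower of 8, 2 lower of 5 and 1 lower of 3 tested members. Whether the pools differed in their content of leukocytes, podocytes or distal nephron cells was not tested.

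Of the differentiated proximal tubule genes, 2 of 18 tested members were higher and 4 lower in female KO (camera adjusted p = 0.0596). The brush border enzyme gene Ggt1 fell from 68.7 ± 7.07 to 35.5 ± 1.42 CPM (edgeR adjusted p = 2.14e-13), and Lrp2 fell by 0.68 ± 0.074 on the log2 scale. In the list of apical endocytosis genes 9 of 17 were lower and 3 higher (camera adjusted p = 0.00504, adjusted p = 0.0619 with an estimated correlation), with the megalin adaptor Dab2 which fell by 0.65 ± 0.039. The vitamin D and phosphate list did not pass as a set (camera adjusted p = 0.322), but 10 of its 17 members rose and 4 fell, with a log2 fold change of -0.94 ± 0.052 for Fgfr2. Of the bile acid genes 3 of 15 were lower and 0 higher (camera adjusted p = 0.653).

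Ribosomal protein genes were again higher for 42 of 51 members (median 0.15, adjusted p = 0.502 with an estimated correlation), with 1.61 ± 0.0317% of counts in female WT and 1.76 ± 0.0756% in female KO (n = 4 each). Immediate early genes had 12 of 18 higher and 2 lower (adjusted p = 0.0580 with an estimated correlation). Fatty acid synthesis (8 of 19 higher, 1 lower), glycolysis (11 of 20 higher, 2 lower) and ATF4 target genes (13 of 22 higher, 2 lower) had adjusted p = 0.0556, 0.157 and 0.476 with an estimated correlation. Across all genes, 2884 were higher and 2585 lower in female KO (edgeR, adjusted p below 0.05), of which 139 and 156 differed by at least 2-fold. With library size as the only scaling, 39.9% of the called genes were higher, against 52.7% as designed. Against a fold of 1.5, 143 were higher and 131 lower, and requiring 5 CPM gave 35 and 48 by 2-fold.

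**Figure D2:**
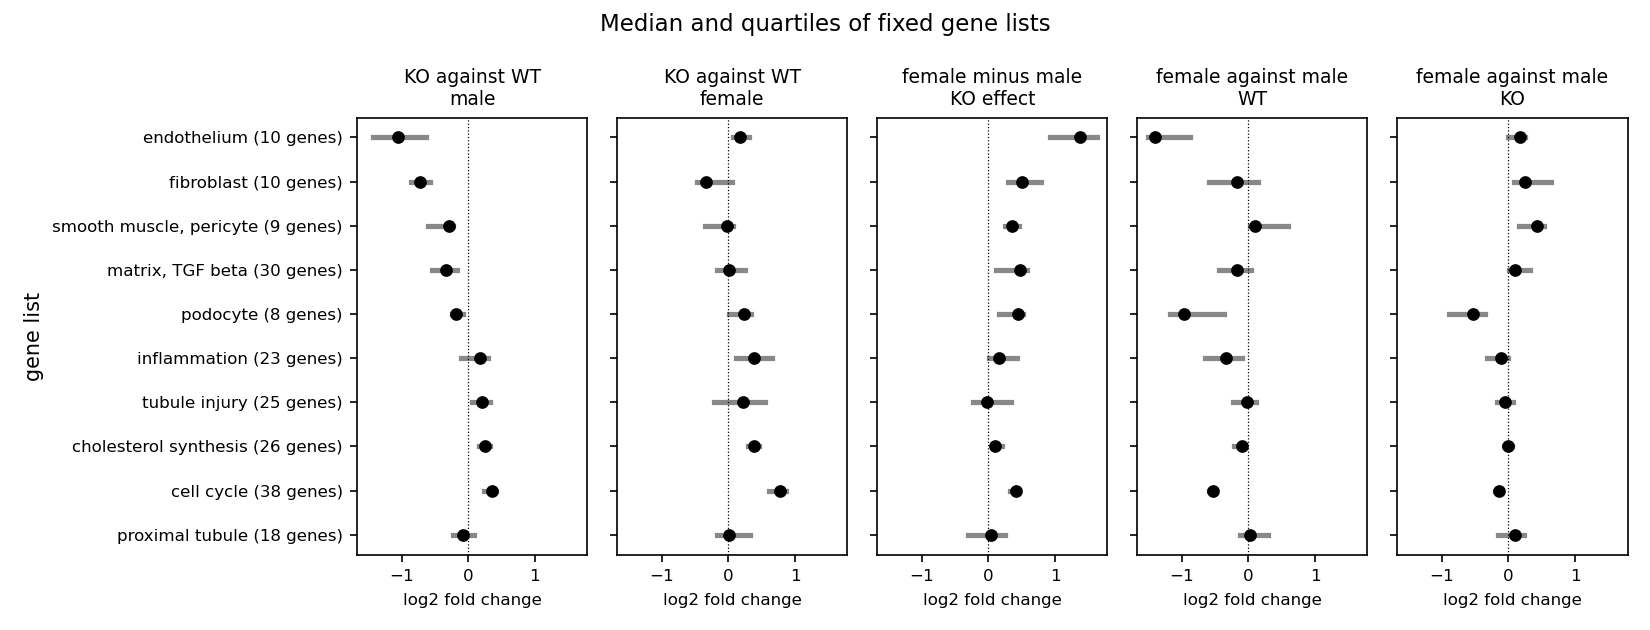
Median log2 fold change of 10 fixed gene lists in 5 comparisons, with horizontal bars from the first to the third quartile of the list members. Cell cycle genes lie to the right of 0 for KO against WT in both sexes (medians 0.36 and 0.77), while endothelial genes lie to the left in males (-1.06) and not in females (0.17).

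Male and female effects were then compared gene by gene, since they come from separate pools and share no library. Both sexes had 1027 genes higher in KO, against 290.8 expected of independent lists of these lengths, and 697 genes lower, against 261 expected. Another 45 genes were higher in male KO and lower in female KO, and 170 the reverse, against 260.7 and 291 expected. The expected counts take genes as independent of each other, but genes of a list such as the cell cycle moved together. The excess over them is therefore no measure of a repeated KO effect. Across genes, which are not independent replicates, the male and female log2 fold changes correlated with a Pearson r of 0.449 and a Spearman rho of 0.433. By at least 2-fold in each sex, 15 genes were higher and 23 lower.

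Thbs2, a matrix glycoprotein (chromosome 17, 14665500 to 14694235), fell by nearly the same amount in each sex, from 49.3 ± 2.89 to 17.6 ± 1.21 CPM in males and from 49.3 ± 3.52 to 19.4 ± 2.05 CPM in females (edgeR interaction adjusted p = 0.379). Among the genes with the largest shared increase were Il5ra, Ptpn22, Unc13d and Vcam1, and Msln, or mesothelin, with log2 fold changes of 0.76 ± 0.042 in males and 1.07 ± 0.041 in females. Icam1 rose by 0.73 ± 0.061 and 1.10 ± 0.061, and Mybl2 by 0.65 ± 0.10 and 1.01 ± 0.11. Shared decreases included Slco5a1, Serpinf1 (-0.97 ± 0.091 and -1.76 ± 0.066), Postn (-1.26 ± 0.073 and -1.17 ± 0.059) and the proprotein convertase gene Pcsk5 (-0.92 ± 0.092 and -1.65 ± 0.083). Cox6b2, a respiratory chain subunit of sperm, fell by 0.91 ± 0.14 and 1.28 ± 0.12, the membrane protein gene Gpm6b by 0.90 ± 0.11 and 0.92 ± 0.095, and the adhesion molecule gene Iglon5 by 0.87 ± 0.13 and 0.95 ± 0.12. Vcam1, Msln, Icam1, Serpinf1 and Pcsk5 shared a direction but passed the interaction test, with the larger effect in females.

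**Figure D3:**
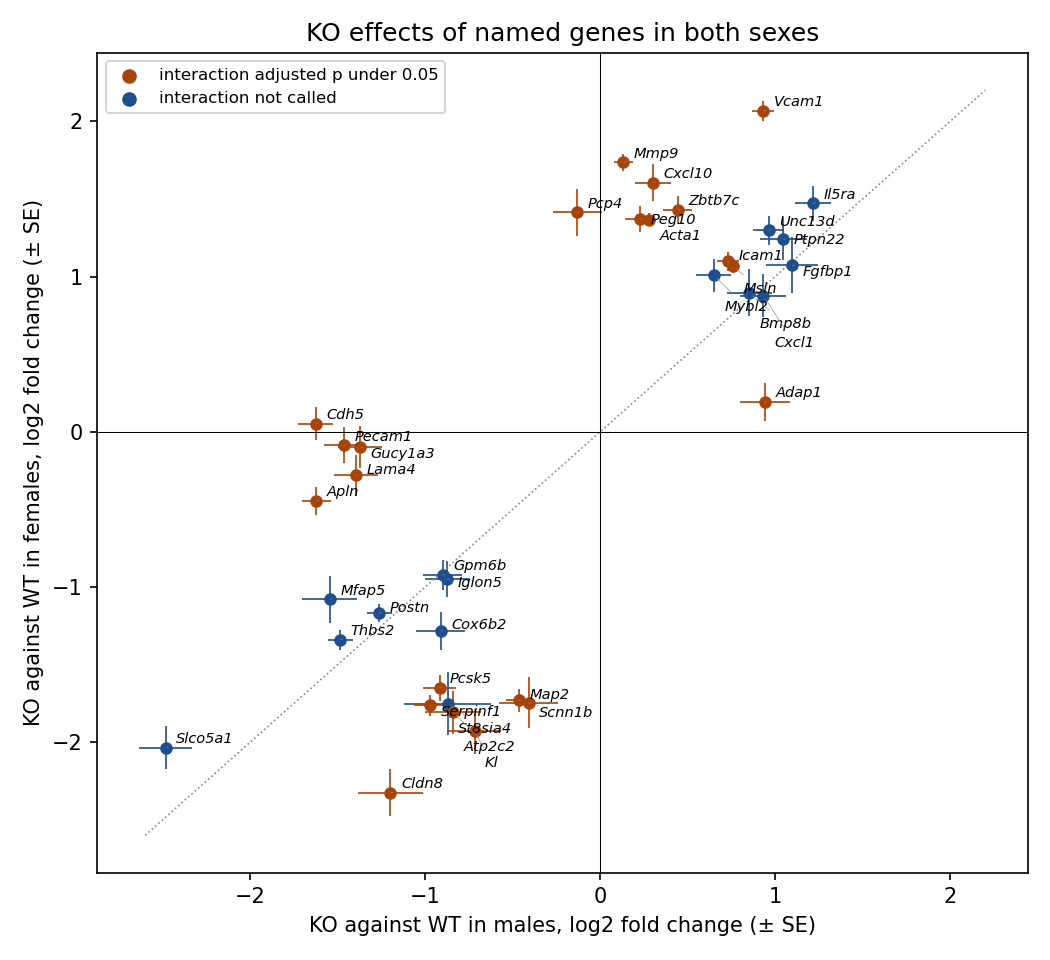
Log2 fold changes of KO against WT in males (horizontal) and females (vertical) for named genes with strong effects in either sex or in both, with SE bars and a dotted line of equal effects. Genes coloured brown passed the interaction test (edgeR adjusted p below 0.05).

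The libraries were also summed into 4 pools and genotype was tested with sex as a covariate, which leaves 1 residual degree of freedom. At an adjusted p below 0.05, edgeR called 0 genes higher and 1 lower. An unadjusted p below 0.05 was reached by 2461 of the 13912 genes tested. The called gene was Thbs2 (adjusted p = 0.0482). The counts above are therefore counts of differences between these pools. Against a fold of 1.5 in each sex, 6 genes were higher and 14 lower in both.

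**Figure D4:**
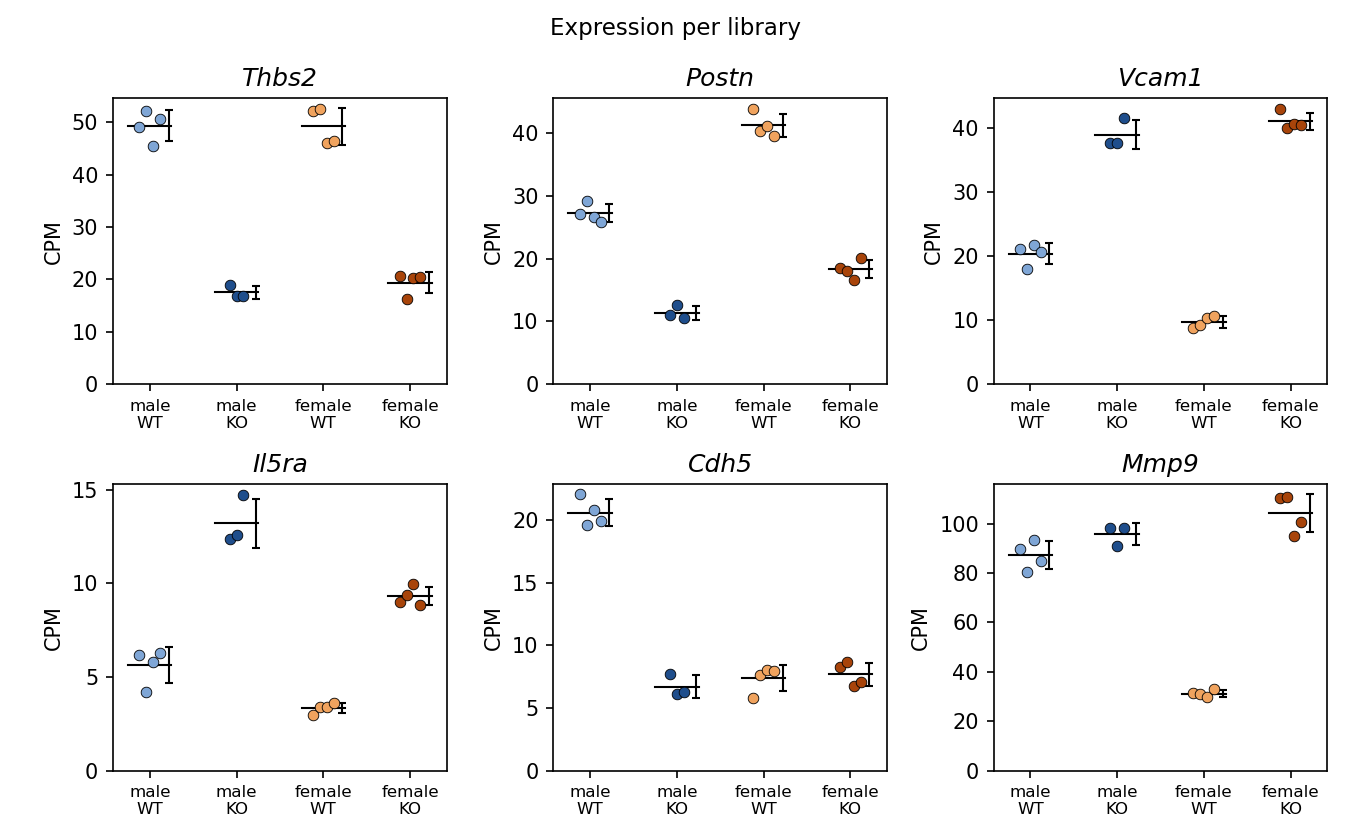
CPM per library for 6 genes in the 4 groups, with 1 point per library, a horizontal line at the group mean and a vertical bar of 1 SD to each side. Thbs2 and Postn are lower in KO in both sexes, and Vcam1 and Il5ra are higher in KO in both sexes. Vcam1, Cdh5 and Mmp9 had different effects in the 2 sexes by the interaction test.

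The interaction term tested whether the KO effect differed between the sexes. It was called for 2177 genes (edgeR, adjusted p below 0.05), 1358 with a more positive effect in females and 819 with a more negative effect. Of these, 215 were called in opposite directions, 471 in the same direction, 1096 in females alone, 331 in males alone and 64 in neither. With library size as the only scaling, 46.3% of the called genes had the more positive effect in females, against 62.4% as designed. Against a fold of 1.5, 44 genes were called.

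Endothelial genes had the largest median difference of the called lists. Of 10 members, 9 had a more positive KO effect in females (median log2 difference 1.38, camera adjusted p = 5.29e-18, 0.00444 with an estimated correlation). Cdh5 was at 7.37 ± 1.04 CPM in female WT and 7.71 ± 0.926 CPM in female KO, near the male KO level, so its male decrease had no female counterpart (edgeR interaction log2 difference 1.68 ± 0.15, adjusted p = 2.81e-10). Esm1, a proteoglycan secreted by endothelial cells, fell by 1.18 ± 0.097 in males and rose by 0.56 ± 0.10 in females, and the integrin gene Itga4 fell by 0.90 ± 0.17 and rose by 0.71 ± 0.19. Matrix and TGF beta target genes had 22 of 30 members with a more positive effect in females and 2 with a more negative one (median 0.48, camera adjusted p = 4.52e-31). The basement membrane collagen gene Col4a1 fell by 0.23 ± 0.039 in males and rose by 0.52 ± 0.037 in females. Fibroblast genes had 7 of 10 with a more positive effect in females (median 0.50, camera adjusted p = 6.94e-10). Cell cycle genes had a more positive effect in females for 29 of 38 members (median 0.41, camera adjusted p = 1.79e-23, 0.00149 with an estimated correlation). The same was found for 9 of 23 inflammation genes (median 0.16, camera adjusted p = 2.22e-05). Epithelial junction genes had 10 of 19 with a more negative effect in females (median -0.15, camera adjusted p = 6.59e-05, 0.0495 with an estimated correlation). Podocyte, smooth muscle, cholesterol synthesis, glycolysis, unfolded protein, ATF4 target, vitamin D and phosphate, and xenobiotic lists were called toward a more positive effect in females. With an estimated correlation these had adjusted p = 0.272, 0.276, 0.323, 0.227, 0.389, 0.476, 0.114 and 0.133.

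Mmp9 was at 87.2 ± 5.64 CPM in male WT and 95.9 ± 4.31 CPM in male KO, and its female increase gave an interaction of 1.60 ± 0.075. Both male groups were near its female KO level, and female WT alone was low. A trait of that single pool and a KO effect in females cannot be told apart. Pcp4 had an interaction of 1.54 ± 0.21. In the other direction, Map2 fell by 0.46 ± 0.079 in males and by 1.73 ± 0.073 in females (interaction -1.27 ± 0.11), Kl fell by 0.72 ± 0.15 and 1.93 ± 0.14 (interaction -1.21 ± 0.22), and Scnn1b and Veph1 had interactions of -1.34 ± 0.24 and -1.17 ± 0.19. Ifit3b, an interferon-induced gene with the near-identical copy Ifit3, which leaves its call uncertain, had an interaction of -1.16 ± 0.19.

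Female WT cells were compared with male WT cells for differences by sex. Beyond Xist and the Y-linked genes, female WT cells had lower levels of endothelial, podocyte and cell cycle genes. Of 10 endothelial genes 9 were lower in females (median -1.41, camera adjusted p = 3.19e-16, 0.00616 with an estimated correlation). This comparison shares its male WT libraries with the male KO comparison and its female WT libraries with the female one. All 8 podocyte genes were lower (median -0.98, camera adjusted p = 9.48e-16, 0.00736 with an estimated correlation), with Nphs1, or nephrin, at 6.48 ± 0.518 CPM in males and 2.29 ± 0.590 CPM in females. All 38 cell cycle genes were lower (median -0.54, camera adjusted p = 4.85e-40, 3.58e-04 with an estimated correlation). Inflammation (15 of 23 lower, 0 higher), NRF2 target (12 of 22 lower, 2 higher) and matrix genes (18 of 30 lower, 4 higher) were also called lower in females, with camera adjusted p = 2.07e-07, 8.05e-06 and 2.08e-11. All 6 genes of the list of Xist and X-linked genes that escape silencing were higher (camera adjusted p = 1.49e-54). Leukocyte, thick ascending limb, smooth muscle and apical endocytosis genes were called higher in female WT, and cholesterol synthesis, fatty acid synthesis, glycolysis and xenobiotic genes lower. With an estimated correlation these had adjusted p = 0.133, 0.126, 0.300, 0.154, 0.312, 0.119, 0.0890 and 0.117. Of other genes, Col11a1, a fibrillar collagen, was at 39.8 ± 2.22 CPM in females and 10.5 ± 1.21 CPM in males (log2 difference 1.92 ± 0.064, edgeR adjusted p = 4.88e-22). The smooth muscle actin Actg2, which shares most of its coding sequence with other actins, differed by 1.87 ± 0.082, the chloride channel regulator Clca3b by 1.57 ± 0.052, Serpinf1 by 1.57 ± 0.064 and the connexin gene Gja5 by -1.94 ± 0.17. Genes known as male-biased in mouse kidney had 2 of 6 tested members lower in females, Odc1 by -0.33 ± 0.029, and those known as female-biased 0 of 3 higher. Neither list passed (camera adjusted p = 0.481 and 0.974). In all, 1757 genes were higher and 2226 lower in female WT (edgeR, adjusted p below 0.05), so 44.1% were higher, against 55.2% with library size as the only scaling. Against a fold of 1.5 there were 62 and 156.

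Female KO and male KO cells differed in fewer genes, 687 higher and 593 lower in females (edgeR, adjusted p below 0.05), or 17 and 7 against a fold of 1.5. Of the called genes 53.7% were higher, against 45.3% with library size as the only scaling. Genes higher in females in both genotypes numbered 236, against 86.8 expected of independent lists, and genes lower in both 273, against 94.9 expected. Another 219 genes were called in opposite directions in the 2 genotypes, against 184.8 expected. Here too the expected counts take genes as independent of each other. The endothelial list had 0 of 10 members called either way (median 0.18, camera adjusted p = 0.424). Smooth muscle and pericyte genes were higher for 7 of 9 (median 0.42, camera adjusted p = 6.39e-22) and fibroblast genes for 5 of 10 (median 0.25, camera adjusted p = 9.85e-10). Podocyte genes were lower for 6 of 8 (median -0.54, camera adjusted p = 6.61e-12, 0.0166 with an estimated correlation), and cell cycle genes for 10 of 38 (median -0.14, camera adjusted p = 1.95e-08, 0.0271 with an estimated correlation). NRF2 targets were lower for 10 of 22 and epithelial junction genes for 9 of 19, with camera adjusted p = 2.32e-06 and 7.64e-06. Leukocyte genes were higher for 8 of 12 in females and matrix genes for 14 of 30, with adjusted p = 0.0663 and 0.0520 with an estimated correlation. Actg2 and Col11a1 were higher in females here too, by 1.55 ± 0.11 and 1.43 ± 0.070, as were the complement gene C1qc (1.37 ± 0.17) and the growth factor gene Igf1 (1.32 ± 0.067), while the phosphatase gene Ptpro, expressed in podocytes, was lower (-1.01 ± 0.11).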

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

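The tests of the cell cycle pattern were chosen after the result was seen. The second endothelial and fibroblast lists were set after those patterns were seen, but before the second lists were scored. The splits of the libraries were planned before their result was seen, but the number drawn over all libraries was raised to 100 after a first run. In groups of 4 libraries a value far from the other 3 was found in 15 of 255 groups, and chance gives such a value in about 1 of 20. The share of counts in the 50 most abundant genes was 15.7% in female WT replicate 4, against a mean of 15.6% in the others. In male WT, Slco5a1 was at 9.52 CPM in replicate 1 (others 12.9), Fgfr2 at 35.6 CPM in replicate 1 (39.3), Cldn8 at 5.28 CPM in replicate 2 (3.45), Col4a1 at 1496 CPM in replicate 2 (1668) and Gpm6b at 12.2 CPM in replicate 3 (9.72). In female WT, Esm1 was at 6.01 CPM in replicate 2 (7.75), Scnn1g at 4.74 CPM in replicate 2 (4.02) and Plvap at 2.25 CPM in replicate 3 (1.35). In female KO, Cldn8 was at 1.10 CPM in replicate 2 (1.81), Thbs2 at 16.3 CPM in replicate 2 (20.4), Acta1 at 79.0 CPM in replicate 3 (86.8), Fgfr2 at 31.6 CPM in replicate 3 (27.3), Gja5 at 2.59 CPM in replicate 3 (1.99) and Cox6b2 at 2.61 CPM in replicate 4 (2.97).

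The KO effect differed between the sexes by the edgeR interaction test for 2177 genes, among them 54 of 80 genes named in the report. Log2 differences, female minus male, were positive for Plvap 1.94, Tie1 1.76, Esm1 1.74, Cdh5 1.68, Pecam1 1.38, Gucy1a3 1.27, Apln 1.18, Lama4 1.11, Gja5 1.09, Myh11 0.87, Col4a1 0.75, Lox 0.67, Vim 0.57, Bgn 0.56, Col1a2 0.48 and Cyr61 0.15. They were also positive for Itga4 1.62, Mmp9 1.60, Pcp4 1.54, Cxcl12 1.36, Cxcl10 1.30, Ccl2 1.17, Peg10 1.14, Vcam1 1.14, Acta1 1.09, Zbtb7c 0.98, Fbln1 0.91, Nphs1 0.61, Ptpro 0.49, Plk1 0.48, Icam1 0.37, Msln 0.31, Fdps 0.23 and Odc1 0.19. They were negative for Scnn1g -1.48, Scnn1b -1.34, Kl -1.21, Cldn8 -1.13, Ggt1 -0.58, Cd24a -0.47, Dab2 -0.28 and Spp1 -0.25. The other negative ones were Map2 -1.27, Veph1 -1.17, Ifit3b -1.16, Atp2c2 -0.97, Clca3b -0.90, Serpinf1 -0.79, Adap1 -0.75, Pcsk5 -0.73, Fgfr2 -0.70, Dcdc2a -0.67, Col11a1 -0.49 and Cdh2 -0.21. Leaving out 1 library ended the call of Fbln1 (without male KO replicate 2, adjusted p = 0.0729), and several single libraries did so for Nphs1 and Ptpro (highest adjusted p 0.102 and 0.0634).

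Median log2 differences of the lists that camera called were 1.38 for endothelium, 0.50 for fibroblasts, 0.48 for matrix, 0.44 for podocytes, 0.43 for xenobiotic genes, 0.41 for the cell cycle, 0.36 for smooth muscle, 0.23 for vitamin D and phosphate, 0.16 for inflammation, 0.11 for glycolysis, 0.10 for ATF4 targets, 0.10 for cholesterol synthesis, 0.084 for the unfolded protein response and -0.15 for epithelial junctions.

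Other splits of the libraries were fitted for each comparison on its own groups. Of 35 splits, 1, the real one, reached its count, with 2546 genes against a highest other of 267 in males, 5582 against 0 in females, 3857 against 0 for sex in WT and 1228 against 50 for sex in KO. The male split with 267 set WT replicates 2, 3 and 4 against the rest. Of 100 drawn splits of all libraries, the real one alone gave 1724 genes called in both sexes (highest other 0) and 2177 interaction genes (highest other 1639). The split with 1639 exchanged every female WT and KO label and so kept the female grouping. Since the libraries of a group are technical replicates of 1 pool, these splits exclude only noise between libraries as the source of the counts. Chance differences between pools or mice are not excluded, and summed per pool edgeR called 0 genes higher and 1 lower in KO, with 2461 at an unadjusted p below 0.05.

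Endothelial genes were lower in male KO than in male WT, while the female groups were both near the male KO level: Cdh5 was at 20.6 ± 1.09 CPM in male WT and 6.71 ± 0.905, 7.37 ± 1.04 and 7.71 ± 0.926 CPM in male KO, female WT and female KO. A second list of 24 endothelial genes, none in a fixed list, had a median male log2 fold change of -0.99, with 14 of 18 tested members lower. In female against male WT 16 of 18 were lower. The values are in line with more endothelial cells in the male WT pool, which the labels describe as proximal tubule cells with no sort named. A Diet1 effect on endothelial cells in males alone stays open, since each group is a single pool.

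Fibroblast genes were lower in male KO and, in part, in female KO, with Postn falling in each sex and Col1a2 at 1541 ± 54.8 CPM in male WT. A second list of 20 fibroblast genes had a median male log2 fold change of -0.52 with 7 of 15 tested members lower. Fewer fibroblasts in the male KO pool would give such values. In females its median was -0.16, with 6 lower and 2 higher, so its members went both ways and do not decide the question. In either sex, fewer fibroblasts and lower expression per cell cannot be told apart, because RNA was measured from whole pools. Lower matrix expression by tubule cells themselves was not tested and stays open.

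Cell cycle genes were higher in KO in both sexes. The male comparison holds no female WT library and had a median of 0.36, so a slow-growing female WT pool does not account for the male part of the pattern. Growth that differs between separate cultures whatever their genotype may contribute, since WT pools of the 2 sexes differed by a median of -0.54, against KO effects of 0.36 in males and 0.77 in females. The KO pools of the 2 sexes differed by less, a median of -0.14 with 10 of 38 members lower in females. Sex of the mice and culture are confounded in these differences, so genotype and culture cannot be told apart for these genes.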

How the results depend on the processing

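Counts of called genes stayed within 1.5 times their value under 3 other scalings, the DESeq2 Wald test, limma-voom, no filter on low counts and a fit of only the groups compared. With 1 library left out at a time, genes higher and lower in male KO ranged from 1010 to 1555 and from 1041 to 1497, and those differing by 2-fold from 25 to 35 and from 96 to 114. The female counts ranged from 2550 to 2968 and from 2293 to 2798, with 130 to 150 and 149 to 172 by 2-fold. Genes called in both sexes ranged from 791 to 1083 higher and from 544 to 740 lower, and interaction genes from 1833 to 2335. Female against male counts ranged from 1451 to 1933 and from 1883 to 2207 in WT, and from 499 to 756 and from 416 to 687 in KO.

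With the stricter filter on low counts, 2-fold genes fell to 4 higher and 27 lower in males and 35 and 48 in females, since that filter removes rarer genes. With glmTreat against a fold of 1.5, 11 were higher and 70 lower in males, of which 7 and 44 had an estimate of at least 2-fold. In females they were 143 and 131, with 62 and 97 by 2-fold. In both sexes 6 were higher and 14 lower, the interaction was called for 44 genes, and sex differences for 62 and 156 in WT and 17 and 7 in KO. That test asks for larger effects by construction.

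Summing counts per pool left 0 genes higher and 1 lower by edgeR, with 2461 at an unadjusted p below 0.05, and it has 1 residual degree of freedom. Thbs2 had an adjusted p of 0.0482, and Postn followed at 0.0581.

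With the replicate block, called genes went from 2808 to 3092 in males, from 5469 to 5909 in females, from 2177 to 2491 for the interaction, from 3983 to 4426 for sex in WT and from 1280 to 1434 for sex in KO. Of 21 pairs of libraries with the same number in different groups, deviations from the group mean correlated between -0.0285 and 0.165, with 17 above 0 and 1 above 0.1. Of 15 libraries 8 correlated best with a library of their own number, against 3.75 expected by chance. This is a hint from the data and not from the design of something shared by number, too weak to read the numbers as pairs.

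With scaling by library size alone, the median log2 fold change of all genes was -0.038 in females, -0.037 for the interaction and 0.028 for sex in WT. That scaling moved the share of called genes that were higher from 52.7% to 39.9% in females, from 62.4% to 46.3% for the interaction, from 44.1% to 55.2% for sex in WT and from 53.7% to 45.3% for sex in KO. Library size alone leaves out the TMM factors, which were 1.01 to 1.02 in female WT and 0.981 to 0.993 in female KO. So small a shift moved these shares because many called effects were small. In females their median absolute log2 fold change was 0.255. Why the factors differed between groups was not tested.

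The genes that met the naming rule, a wider set than those printed, made 504 pairs of a gene and a comparison in which it was called. None reversed under the alternatives run, but the rule took called genes with the largest folds from these same counts. A reversal was therefore unlikely from the start. The pairs that lost their call numbered 378 with glmTreat, 28 with the DESeq2 Wald test, 19 without a filter and 12 with limma-voom. Scaling ended 18 with library size only, 8 with the upper quartile and 5 with DESeq2 size factors. A fit of only the groups compared ended 12, the replicate block 2 and leaving out some library 109. The stricter filter ended 4 and kept 427, and the other pairs were not tested with it. Camera called 70 lists with the preset correlation, 35 with an estimated one, and fry 123. Fry does not compare a list with other genes.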

Other observations

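No technical-replicate pair was a duplicate library: the chi-square over its degrees of freedom for 21 pairs within groups ranged from 1.51 to 7.30. The share of counts in immediate early genes was 0.188 ± 0.00154% in female WT and 0.207 ± 0.00705% in female KO (n = 4 each), and in males 0.193 ± 0.00172% in WT (n = 4) and 0.206 ± 0.00434% in KO (n = 3).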
